A study of Rattus norvegicus with 24 samples.

How the data were processed

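Hearts of male Wistar rats (outbred RccHan stock) were profiled after daily gavage with 800 mg/kg metformin, a biguanide given to people for type 2 diabetes, or with vehicle for 1, 3 or 14 days. Per the labels, RNA came from the apex of the left ventricle and was hybridised as biotin-labelled single-stranded cDNA to 1-colour Affymetrix arrays, with 1 array per animal. The 24 arrays form 6 groups of 4 (control and metformin on each day). The study's design text gives 5 animals per group, of which 4 per group are analysed here. Groups and replicate numbers were taken from the sample titles.

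The value table holds linear intensity values that the authors normalized and deposited as 1 value per array and transcript cluster, the array's unit for a gene or part of one. RMA is named in the submitters' processing notes, and its software, version and settings are not given in the sources used here. All 1652208 values were above 0. The highest value on each array lay between 999433 and 999974, which is above what a scanner of this type can record, so the scale is not that of the scanner. Fold changes may therefore be stretched against fold changes in RNA, and values close to that ceiling are compressed. The log2 medians of the arrays ran from 4.68 to 4.95 and the 99th percentiles from 16.9 to 17.6. Correlations between arrays on the log2 scale, over all features, ran from 0.984 to 0.992, and no arrays held identical values. The number of arrays limits the precision of every value below.

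The tests had been planned for log2 values. Since the deposited intensity values were linear, log2 was taken first and the tests were kept. Of 68842 transcript clusters, 23951 had a gene symbol in the platform annotation, 23446 of them exactly 1 and 505 several, and 44891 had none there. Symbols were updated through the RefSeq gene table of assembly GRCr8, used for names only: 22077 single-symbol clusters matched by gene ID, 1227 by current symbol and 127 by synonym, 15 kept the platform symbol, and 128 symbols changed. Clusters with several symbols named no gene. A gene with several clusters was represented by the one with the highest mean over all arrays, and a gene was tested if it lay above its array's median on at least 4 arrays. This left 16031 of 22037 genes.

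Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (statmod 1.5.0). A linear model with 1 mean per group was fitted to all 24 arrays, so that all comparisons share the estimate of spread, with moderated statistics and Benjamini-Hochberg adjustment over the 16031 genes of a comparison. A gene was called at an adjusted p under 0.05. The comparisons were metformin minus control on each day and its mean over the 3 days, a moderated F statistic for a treatment effect that differed between days, and the same F statistic for the control days. Standard errors (SE) are those of the moderated fit. Adjusted p values below are from limma unless another test is named.

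A total of 41 lists (27 pathways or responses and 14 sets of cell type markers) were tested with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over the lists of a comparison and lists of at least 3 tested members. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. A list score per array was the mean over members of the log2 value minus that member's mean over all arrays. The score was compared within days by exact permutation of the arms, 70 reassignments a day and 343000 for the 3 days together, two-sided. With 4 against 4 arrays the smallest exact p of a day is 0.0286.

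Named genes followed a fixed rule. For each day and for the mean of days, it took up to 10 risen and 10 fallen genes with the largest change among called genes whose arms did not overlap, on each day in the case of the mean. Where fewer than 5 passed, it took the 10 genes with the smallest p. For both F statistics it took the 6 genes with the smallest p, for lists up to 4 members with the smallest p, of which fewer are named here, a choice made after their values were seen, and 18 genes of fuel use, cardiac stress and metformin transport were always included. Genes with placeholder names were counted and not named, and some of the genes always included are not reported here. The groups, lists, tests, naming rule and most alternative settings were fixed before the data were examined. The exact permutation of list scores, cyclic loess between arrays, the covariates and the joint removal of 2 arrays were chosen after seeing the data, as were Bmal1 and Nr1d1 as named genes.

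The clock score per array was computed from 10 genes of the clock list, after seeing the data. The procedure was tested on simulated data made from the real means and spreads of the 16031 genes, with 50 changed genes at each of 4 fold sizes. At a 1.5-fold change it recovered 68% on day 1, 72% on day 3, 70% on day 14 and 92% for the mean of days, and at 2-fold 98%, 98%, 96% and 98%. For the test of treatment by day it recovered 52% at 1.5-fold and 88% at 2-fold, and for control days 78% and 96%. Unchanged genes called in these simulations numbered 11 for day 1, 6 for day 3, 9 for day 14, 12 for the mean of days, 6 for treatment by day and 22 for control days. The simulated noise was drawn independently for each gene and array, and the changed genes of all 4 fold sizes were planted together. The simulated data thus held no correlation between genes, no outlying array and no trend with intensity. These rates may therefore overstate what the real data allow. Alternatives covered the filter, the choice of cluster, the scaling between arrays, the variance model, array weights, the threshold, the arrays in the fit, blocks by replicate number and leaving out each array. The labels give no cage, necropsy time, hybridisation batch or RNA quality value for an animal, so these were not modelled. Lactate and histology, which the design text mentions, were not analysed here.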

Results

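The study asked how the left ventricle of the rat responds to a high oral dose of metformin over time. Transcript levels were measured in 4 hearts per arm on days 1, 3 and 14. Differences are given as metformin minus control on the log2 scale, with n = 4 per arm.

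After 1 day of dosing no gene was called by limma, with 1078 genes at an unadjusted p under 0.05 against 802 expected by chance. The smallest adjusted p was 0.187. The genes with the smallest p, none past the threshold, were lower for Rpl36l6 (-0.71), Bex3 (-0.58), Dlc1 (-0.59), Casq1 (-1.01), Sema5a (-0.54), Sun2 (-0.29), Rogdi (-0.31) and Ubcl1 (-0.58), and higher for Tbx3 (0.47) and Cept1 (0.33). Casq1 encodes the calsequestrin of fast skeletal muscle and Tbx3 a transcription factor of the conduction system. Zbtb16, a transcription factor induced by glucocorticoids, differed by 2.02 (SE 0.47) with an adjusted p of 0.226.

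On day 1 camera called 7 of the 41 lists, and with an estimated correlation it called 0, with an adjusted p of 0.794 for each of the 7. No member of these lists was called over all genes. The PPAR-alpha list had a median difference of 0.18 over 20 measured members, of which 16 were higher, and the endoplasmic reticulum chaperones one of 0.06 over 18, with Hspa5 at 0.31. The glucocorticoid list had a median of -0.25 over 22, the FOXO and atrophy list -0.16 over 23, and the sterol synthesis list -0.13 over 19, with Insig1 at -0.59. Adjusted over the list alone, 1 glucocorticoid gene was higher and 3 lower, 1 FOXO gene was lower and 2 sterol genes were lower. The remaining 2 lists were markers of other tissues. The erythroid markers had a median of -1.17 over 7 members, with Hbb-bs, a beta-globin, at -1.28 (SE 0.48). The skeletal muscle markers had a median of -0.34 over 6, and this rested on replicate 4 of the day 1 controls, where Myh4, a fast skeletal myosin, stood at 9.67 against 5.29 to 5.34 in the other controls of that day. Without that array the list's adjusted p was 0.329 with the opposite direction, the highest of a range from 0.000576 over the arrays left out, and the Myh4 difference was 0.05. The skeletal muscle call was also lost without metformin replicate 2 (adjusted p = 0.116) or 4 (0.0728), the chaperone call without control replicate 3 (0.0516) or metformin replicate 2 (0.116), the glucocorticoid call without control replicate 3 (0.216) and the FOXO call without metformin replicate 2 (0.0519). The number of lists called was 14 without metformin replicate 1, 4 without metformin replicate 2 and 12 without control replicate 4.

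After 3 days 76 genes were called by limma, 8 higher and 68 lower with metformin, and in all 76 the arms did not overlap. Of all 16031 genes, 1021 had arms that did not overlap, where chance gives 2 in 70. Among these genes the largest falls were in Dcxr, which reduces dicarbonyls and xylulose (-1.21, 2.32-fold lower, SE 0.17, adjusted p = 0.00157), and in Phkg1, the catalytic subunit of muscle phosphorylase kinase (-1.21, 2.31-fold lower, SE 0.15, adjusted p = 0.000596). Phkg1 stood at 8.22 ± 0.34 (SD, n = 4) in controls and 7.02 ± 0.17 with metformin. Other large falls were in Tmem71 (-0.88), Ypel2 (-0.87), Klhl33 (-0.87), the guidance protein gene Sema5a (-0.82), Corin (-0.81), whose protease activates natriuretic peptides, Gstm7 (-0.80), Tgm1 (-0.79) and Bcat2 (-0.76).

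The 8 genes that rose on day 3 were Slc25a5l1 (0.65), Tstd3 (0.63), Tubb4b, a beta-tubulin (0.63, SE 0.09, adjusted p = 0.0019), a cluster under the platform symbol EVX1 (0.62), whose identity as a rat gene is not settled here, Clec9a, a dendritic cell receptor (0.51), Pmm2 (0.43), Slc25a5 (0.34), an adenine nucleotide carrier of mitochondria, and Myo1c (0.27). Slc25a5l1 and Slc25a5 are closely related in sequence, so the array may not measure them separately. The number of calls depended on single arrays. It was 27 without control replicate 2, 144 without control replicate 3, 29 without control replicate 4, 45 without metformin replicate 1 and 39 without metformin replicate 4, and 3 with only the 8 arrays of that day in the fit. After a second quantile normalization 42 were called, and with each array centred on its median 37. Of 21 genes named for this day as called, 9 (Tubb4b, Pmm2, Dcxr, Phkg1, Sema5a, Gstm7, Tgm1, Bcat2 and Ivd) were called without each of the 8 arrays in turn, and 12 were not; the EVX1 call was lost without any 1 of them. Of the same 21 calls, 5 were lost after the second quantile normalization, 5 with centring, 3 after cyclic loess, 7 with the erythroid marker level as a covariate, 9 with the clock score as a covariate (Ypel2, Corin and Aldh6a1 among them) and 11 without both arrays that were high in muscle or blood markers. With only the 8 arrays of that day 20 of the 21 calls were lost, Dcxr being the exception. With the replicate block within day 13 were lost.

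As a list, genes of branched-chain amino acid and ketone oxidation were lower on day 3, and the members called were all of the branched-chain part. Of 17 measured members 4 fell, 0 rose and 13 did not pass, with 8 falling when adjusted over the list alone, and the median difference was -0.27. Ivd, isovaleryl-CoA dehydrogenase of leucine breakdown, fell by 0.63 (SE 0.09, adjusted p = 0.00131). Bcat2, the mitochondrial transaminase that starts the pathway, stood at 9.92 ± 0.31 in controls and 9.16 ± 0.04 with metformin (SD, n = 4). Ppm1k, the phosphatase that activates the branched-chain ketoacid dehydrogenase, fell by 0.63 and Aldh6a1 of valine breakdown fell by 0.28, and each of these calls was lost without any 1 of 7 of the 8 arrays. Camera gave an adjusted p of 2.63e-10 for the list, fry 0.000916, and camera an adjusted p of 0.0654 with an estimated correlation. The difference in list score was -0.30 (SE 0.06), and the two-sided exact permutation p was 0.0286, the smallest that 4 against 4 arrays can give. This p was not adjusted over the 41 lists, and the mast cell markers reached it on day 3 too.

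Camera called 6 further lists on day 3, and none of them held with an estimated correlation. PPAR-alpha genes had a median of 0.23, with 16 of 20 members higher, 0 called, and 3 higher when adjusted over the list alone; Aqp7, a glycerol channel, differed by 0.91. The adjusted p was 8.23e-06 with camera and 0.141 with an estimated correlation. Fatty acid oxidation genes had a median of 0.15 over 21 members, 0 called, with Eci2 at 0.31, Slc25a20 at 0.37 and Cpt1b at 0.29 against Echs1 at -0.33. Their adjusted p was 0.929 with an estimated correlation, and the camera call was lost without control replicate 3 (adjusted p = 0.237) or metformin replicate 1 (0.226). FOXO and atrophy genes had a median of -0.20 over 23, 0 called and 8 lower when adjusted over the list alone, with Foxo1 at -0.47 and Insr, the insulin receptor, at -0.40, and an adjusted p of 0.141 with an estimated correlation. Immediate-early genes had a median of -0.24 over 25, with Nr4a1 at -1.60 (adjusted p = 0.929 with an estimated correlation), and NRF2 antioxidant genes one of -0.09 over 19, with Nqo1 at -0.58 (adjusted p = 0.649 with an estimated correlation). The immediate-early call was lost without control replicate 3 (adjusted p = 0.745) or metformin replicate 3 (0.0522), and the NRF2 call without control replicate 1 (0.0512) or 3 (0.144) or metformin replicate 3 (0.0681) or 4 (0.0915). With the clock score as a covariate the immediate-early (adjusted p = 0.294), NRF2 (0.118) and mast cell (0.118) calls were lost, and the NRF2 call also without both arrays high in muscle or blood markers (0.0532). Mast cell markers had a median of 0.38 over 5, with the chymase gene Cma1 at 0.57 (adjusted p = 0.141 with an estimated correlation). The erythroid markers were high in control replicate 2 of that day, at a list score of 1.53 against -0.28 to -0.11 in the other controls.

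**Figure D1:**
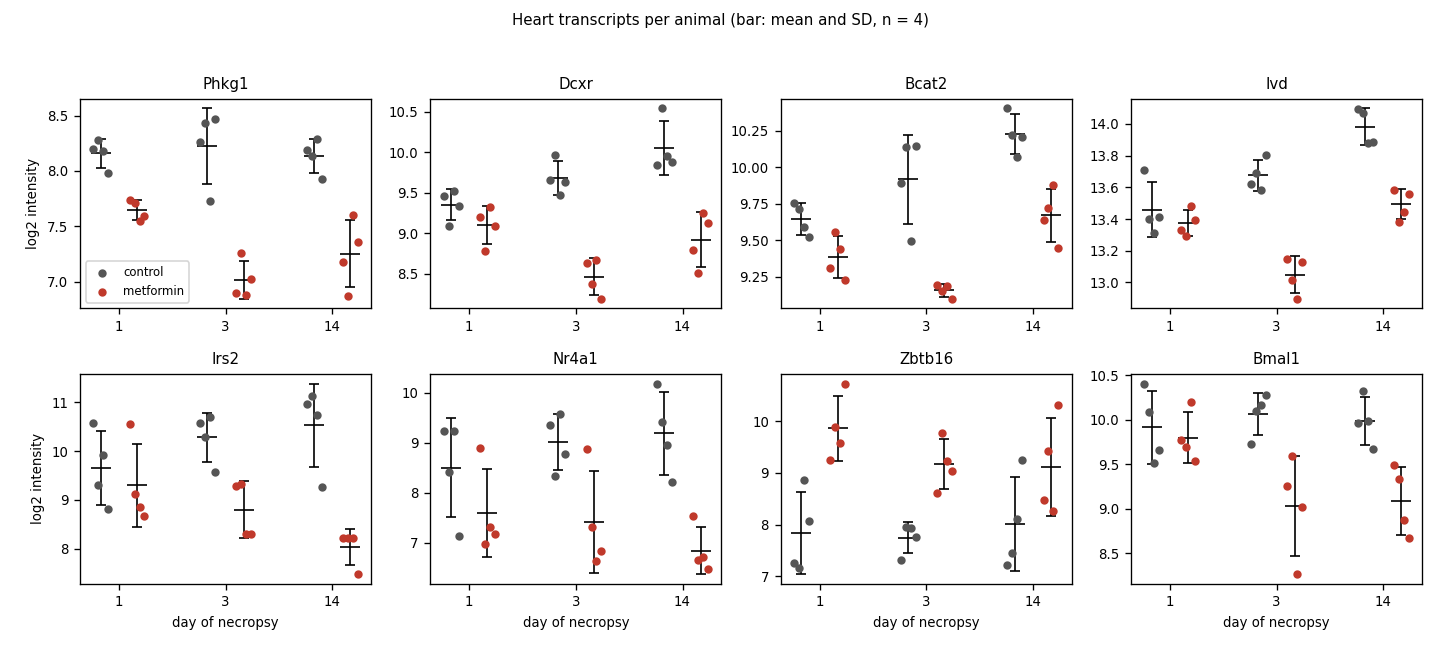
Log2 intensity (vertical axis) of 8 genes by day of necropsy (horizontal axis); each point is 1 animal, grey for control and red for metformin, and the bars give the mean and SD of 4 animals. On day 3 the metformin arm lies below the control arm for Phkg1, Dcxr, Bcat2 and Ivd, with no overlap.

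After 14 days 45 genes were called by limma, 2 higher and 43 lower, and in all 45 the arms did not overlap. Of all 16031 genes, 983 had arms that did not overlap on day 14, where chance gives 2 in 70. Irs2, an adaptor of insulin signalling, fell by 2.48 on the log2 scale (5.59-fold lower, SE 0.44, adjusted p = 0.016), from 10.52 ± 0.85 to 8.04 ± 0.37 (SD, n = 4). Other falls were in Vsnl1, a neuronal calcium sensor (-1.23), Dcxr (-1.13), the clock gene Per1 (-1.10), the magnesium transporter Slc41a3 (-0.90), Phkg1 (-0.88), the splicing factor Srsf3 (-0.66), Selenbp1 (-0.63), Lsamp (-0.60) and Ppp1r10 (-0.59). The 2 genes that rose were Scn3b, a sodium channel subunit (0.51, SE 0.10, adjusted p = 0.0372), and Ppp1r14b (0.46, adjusted p = 0.0214). The number of calls was 28 without control replicate 1, 16 without control replicate 2, 17 without control replicate 3, 11 without metformin replicate 2, 142 without metformin replicate 3 and 28 without metformin replicate 4, and 0 with only the 8 arrays of that day in the fit. After a second quantile normalization 8 were called, with each array centred on its median 12 and after cyclic loess 16. Of 14 genes named for this day as called, Dcxr, Srsf3 and Lsamp were called without each of the 8 arrays in turn, and the Irs2 call was lost without control replicate 1 (adjusted p = 0.0509), 2 (0.0622) or 3 (0.0612) or metformin replicate 2 (0.0509) or 4 (0.0524), and with the clock score as a covariate (-1.99, 0.0648). Of the 14 calls, 8 were lost after the second quantile normalization, 6 with centring, 5 after cyclic loess and 9 with the clock score as a covariate. With the replicate block within day 8 were lost.

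The branched-chain and ketone oxidation list was lower on day 14 too, with 2 of 17 members falling, 0 rising, 4 falling when adjusted over the list alone, and a median of -0.20. Ivd fell by 0.49 (SE 0.09, adjusted p = 0.0153) and Bcat2 fell by 0.56 (adjusted p = 0.0462), a call lost without any 1 of 7 of the 8 arrays. Both calls were lost after a second quantile normalization (adjusted p = 0.0922 and 0.0848), centring (0.102 and 0.112), cyclic loess (0.0548 and 0.0981) and with the clock score as a covariate (0.0604 and 0.105), while Bckdha, a subunit of the branched-chain ketoacid dehydrogenase, stood at -0.38 and did not pass. The adjusted p of the list was 1.28e-05 with camera and 0.517 with an estimated correlation, and the exact permutation p of its score was 0.0286. This permutation p was not adjusted over the lists. The FOXO, NRF2, AMPK and nerve and glia lists reached it on day 14 too. Of 23 FOXO and atrophy genes, 1 (Irs2) fell and 6 were lower when adjusted over the list alone, with a median of -0.14 and an adjusted p of 0.517 with an estimated correlation. Of 22 glucocorticoid genes, 1 (Per1) fell, the median was -0.34, and Zbtb16 stood at 1.11 in the other direction; the adjusted p was 0.816 with an estimated correlation. Immediate-early genes had a median of -0.30 over 25, with Nr4a1 at -2.35 and Nr4a2 at -1.73 not past the threshold (adjusted p = 0.881 with an estimated correlation). Fatty acid oxidation genes had a median of 0.11 over 21 (adjusted p = 0.918 with an estimated correlation) and cardiac stress genes one of 0.20 over 19, with Acta1, skeletal alpha-actin, at 0.79 and Nppb, brain natriuretic peptide, at 0.99 (adjusted p = 0.816 with an estimated correlation). The glucocorticoid call was lost without metformin replicate 2 (adjusted p = 0.0558) or 3 (0.057), the cardiac stress call without metformin replicate 2 (0.0825) or 3 (0.057), and the immediate-early call without control replicate 1 (0.0769) or metformin replicate 1 (0.0503) or with the clock score as a covariate (0.0921). The fatty acid call was lost without control replicate 2 (0.0553) or 3 (0.171) or metformin replicate 1 (0.148) or 2 (0.174), and 3 lists were called in all without metformin replicate 2.

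The lists of days 3 and 14 shared 18 of their 68 and 43 lower genes, where independent lists of these sizes would share 0.18, and none of the higher genes. Days 3 and 14 have no animal in common, but both comparisons share 1 estimate of spread per gene from all arrays. On both days the differences correlated negatively with mean intensity across genes (Spearman rho -0.108 on day 3 and -0.377 on day 14). The overlap is thus no independent replication, and 0.18 is not its value in the absence of a treatment effect. The day 14 list held 10 lower genes without metformin replicate 2 and 7 after a second quantile normalization. The shared genes included Phkg1, Dcxr, Bcat2, Ivd, Selenbp1, Mylk3, Cdon and Adamtsl4. Of the 76 genes called on day 3, 73 had the same sign on day 14 and 72 on day 1, with a median difference of -0.44 on day 3, -0.30 on day 14 and -0.17 on day 1.

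Averaged over the 3 days, 708 genes were called by limma, 104 higher and 604 lower, or 85.3% lower. With each array centred on its median 482 were called and 68.5% were lower, and after a second quantile normalization 384 were called and 69.0% were lower. With the erythroid marker level as a covariate 379 were called, and with the clock score 437. The erythroid markers themselves had a median of -0.62 in this comparison, with all 7 members lower and 0 called (adjusted p = 0.108 with camera). Among the 29 called genes whose arms did not overlap on any day, the largest falls were in Phkg1 (1.83-fold lower, SE 0.09, adjusted p = 1.01e-05), Klhl33 (-0.63), Acsf2 (-0.51), an acyl-CoA synthetase, Mylk3 (-0.49), the cardiac myosin light chain kinase, Adam19 (-0.48), Tgfbi (-0.47), Cdon (-0.45), Prdm16 (-0.43), Pcp4l1 (-0.42) and Adamtsl4 (-0.41). The 2 that rose were Slc25a5l1 (0.43) and Prr5l (0.23).

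In the mean of days the FOXO and atrophy list was lower, with 5 of 23 members falling, 0 rising and 18 not passing, 13 falling and 1 rising when adjusted over the list alone, and a median of -0.18. The members that fell included Foxo1 itself (-0.42), Irs2 (-1.44), and the muscle ubiquitin ligases Fbxo32 (-0.71, SE 0.11, adjusted p = 0.000832) and Trim63 (-0.39). The adjusted p was 5.48e-06 with camera and 0.108 with an estimated correlation, and the exact permutation of the list score within days gave p = 2.92e-05, adjusted over the 41 lists 0.0012. Branched-chain and ketone oxidation genes had 7 of 17 falling, 10 when adjusted over the list alone, and an adjusted permutation p of 0.00897, against an adjusted p of 0.108 with camera and an estimated correlation. PPAR-alpha genes had 2 of 20 rising (Slc25a20, the carnitine carrier, at 0.27, and Cpt1b, muscle carnitine palmitoyltransferase, at 0.18), 9 when adjusted over the list alone, and an adjusted permutation p of 0.0255 (adjusted p = 0.21 with camera and an estimated correlation). The Cpt1b call was lost without any 1 of 16 of the 24 arrays and with the erythroid covariate (0.0704) or the clock covariate (0.0928), and the Slc25a20 call with the erythroid covariate (0.0603) or without both arrays high in muscle or blood markers (0.0561). Immediate-early genes had 2 of 25 falling, Nr4a1 (-1.62, SE 0.31) and Nr4a2 (-0.98, a call lost with the clock covariate, -0.71, adjusted p = 0.173), and an adjusted permutation p of 0.0271. Sterol synthesis genes had 2 of 19 falling, Insig1 (-0.50) and Fdft1, squalene synthase (-0.35), and an adjusted permutation p of 0.0183; its camera call was lost without day 3 control replicate 3 (adjusted p = 0.0565) or day 1 metformin replicate 3 (0.0554). The other camera calls were fatty acid oxidation, with 3 members rising and 1, Etfb, falling, a call lost without any 1 of 12 arrays (adjusted permutation p = 0.187), and endoplasmic reticulum chaperones, with 0 called (0.363), a list call lost without any 1 of 12 of the 24 arrays (adjusted p of 0.0528 to 0.166). Without day 1 control replicate 4, 12 lists were called. After a second quantile normalization the adjusted permutation p was 0.0969 for branched-chain genes, 0.0678 for sterol genes and 0.0678 for immediate-early genes, and with each array centred on its median it was 0.0777 for immediate-early genes. None of the 7 held with camera and an estimated correlation, where the last 4 had an adjusted p of 0.81.

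**Figure D2:**
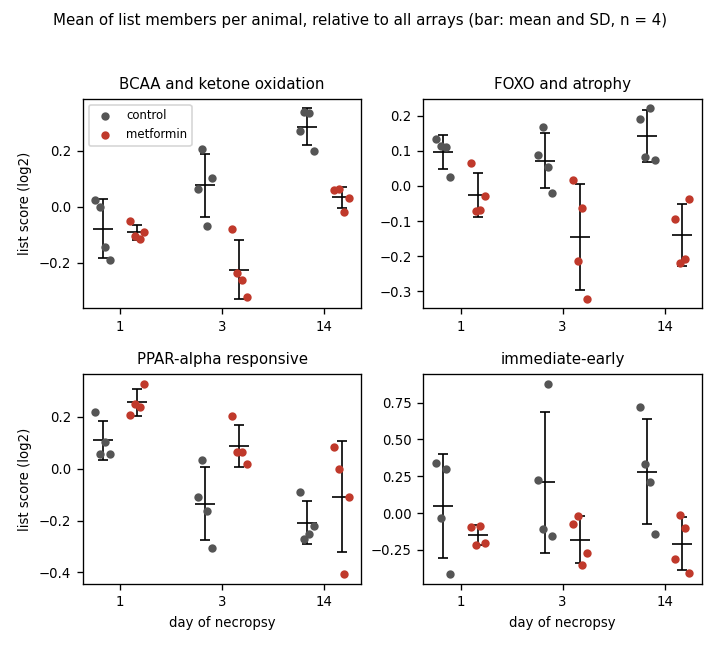
Score of 4 gene lists (vertical axis, mean over members of log2 intensity minus the member's mean over all arrays) by day of necropsy (horizontal axis); points are animals, grey for control and red for metformin, and bars give the mean and SD of 4 animals. The branched-chain score of the controls goes from -0.08 on day 1 to 0.28 on day 14, and that of the metformin arm from -0.09 to 0.03.

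Lists tied to known actions of metformin were measured too. Glycolysis and lactate handling genes had a median of -0.01 in the mean of days over 24 members, with 2 falling, and complex I subunits, a proposed target of metformin, one of -0.03 over 34 with 0 called. Neither was called by camera (adjusted p of 0.812 and 0.317). The list of AMPK subunits and biogenesis regulators had a median of -0.04 with 3 of 22 falling, among them Ppargc1a, the mitochondrial coactivator (-0.52, SE 0.12, adjusted p = 0.0131), a call lost with the clock covariate (adjusted p = 0.0848). The adjusted permutation p of this list was 0.0183, and it was 0.419 after a second quantile normalization, 0.278 with centring and 0.107 after cyclic loess. Targets of the integrated stress response had a median of -0.02 over 31 with 1 falling, and metformin transporters one of -0.05 over 8 with 0 called. The lactate dehydrogenase genes Ldha (-0.03, SE 0.03) and Ldhb (0.03, SE 0.03) and the lactate carrier Slc16a1 (0.02, SE 0.08) did not pass. The same held for Pdk4 (0.26, SE 0.31), Txnip (0.17, SE 0.24), Angptl4 (0.27), Ucp3 (0.12), Cpt1a (0.07), Nppa (-0.03, SE 0.47), Nppb (0.37), Myh7 (-0.02), Gdf15 (0.09) and the organic cation carriers Slc22a3 (-0.17) and Slc29a4 (-0.06). Fgf21 lay below the intensity filter. The mean log2 values of Slc29a4 (4.68), Angptl4 (5.08) and Gdf15 (5.10) lay close to the array medians (4.68 to 4.95). A change in these dim genes could therefore be missed.

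No gene had a treatment effect that was shown to differ between days. The moderated F statistic of limma called 0 genes, with 794 at an unadjusted p under 0.05 against 802 expected by chance. The smallest p belonged to Tubb4b (adjusted p = 0.258), at 0.11 on day 1, 0.63 on day 3 and -0.17 on day 14. Cyria, Prmt9, Slc41a3, Cds2 and Krtap12-2 followed with an adjusted p of 0.686. For the branched-chain list, the day 3 effect minus the day 1 effect was a score of -0.29 (95% interval -0.46 to -0.11), and the day 14 effect minus the day 1 effect was -0.24 (-0.41 to -0.07). Camera gave adjusted p values of 2.2e-07 and 0.00272 for these differences, and 0.154 and 0.904 with an estimated correlation.

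In the vehicle controls alone 26 genes differed between days by limma, 22 of them higher and 4 lower on day 14 than on day 1. Pyruvate carboxylase, Pc, was higher by 0.56 (SE 0.07, adjusted p = 0.00399), Igdcc4 by 0.46, Fam162a by 0.47 and Usp4 by 0.32. Adamts12, a matrix protease (-0.92, SE 0.13, adjusted p = 0.00434), and the uncoupling protein Ucp3 (-0.98, adjusted p = 0.0161) were lower. Among 17 branched-chain and ketone oxidation genes 4 rose from day 1 to day 14 and 13 when adjusted over the list alone, with a median of 0.36 and an adjusted p of 0.0098 with camera and an estimated correlation, the only list called that way in this comparison. The adjusted p was 0.165 with only the control arrays in the fit, 0.0764 with centring and 0.11 with the erythroid marker level as a covariate, which end the call, and 0.0028 to 0.0272 without any 1 control array. The day 14 controls enter both this rise and the difference from metformin on day 14, so these values are not independent. Cell cycle genes had a median of -0.34 with all but 1 of 30 members lower and 0 called, erythroid markers one of -1.39 and PPAR-alpha genes one of -0.21, with adjusted p values of 0.466, 0.4 and 0.2 with an estimated correlation, and these 3 lists were tested under no other setting here. The count of 26 fell to between 3 and 15 when any control array other than day 3 replicates 2 and 3 was left out. It was 0 with only the control arrays in the fit, 0 with the erythroid marker level as a covariate, 5 with centring, 6 after cyclic loess, 16 with the clock score as a covariate and 9 without both arrays high in muscle or blood markers, while a second quantile normalization gave 34.

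**Figure D3:**
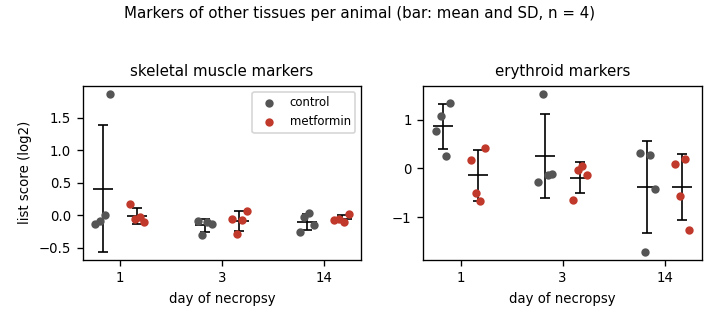
Scores of skeletal muscle and erythroid markers (vertical axis, mean of log2 intensity relative to all arrays) by day of necropsy (horizontal axis); points are animals, grey for control and red for metformin, and bars give the mean and SD of 4 animals. One day 1 control lies at 1.87 for skeletal muscle markers and one day 3 control at 1.53 for erythroid markers.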

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

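The tests with cyclic loess, the clock covariate and fatty acid against branched-chain genes, the clock score test, the exact permutation of list scores and the removal of both arrays were chosen after the results were seen. In the groups of 4 arrays, 35 of 660 sets of values (genes named in the text and list scores) held 1 array far from the other 3, where chance gives about 33, or 1 in 20.

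Day 1 control replicate 4 lay far from its group for skeletal muscle markers (score 1.87 against -0.14 to 0.01), with Myh4 at 9.67 (others 5.29 to 5.34), and also for Corin at 13.15, Vsnl1 at 6.55, Ppargc1a at 12.95 and Myh7 at 18.05, each below the others. Day 3 control replicate 2 lay far for erythroid markers (1.53 against -0.28 to -0.11), Hbb-bs at 18.53 (others 16.88 to 16.99), Adamts12 at 10.29 and Myh4 at 4.91. Without both arrays 29 genes were called on day 3, 64 on day 14 and 510 in the mean of days. Day 1 control replicate 1 stood apart for Slc25a20 at 12.49 and Etfb at 14.55, and replicate 2 for Insig1 at 9.22. Among day 14 controls, replicate 1 stood apart for Scn3b at 5.37 and Fbxo32 at 15.24, replicate 2 for Dcxr at 10.54 and Ldhb at 17.47, and replicate 4 for Pmm2 at 7.95, Tgm1 at 5.54, Pdk4 at 11.8 and the mast cell score at -0.01. In the metformin arm, day 1 replicate 1 stood apart for Per1 at 8.29 and Nr1d1 at 7.21, replicate 2 for Mylk3 at 15.52, replicate 3 for Acta1 at 18.5, and replicate 4 for Cdon at 7.49, Cyria at 11.88 and Usp4 at 12.59. Day 3 replicate 3 stood apart for Vsnl1 at 5.02. On day 14, replicate 2 stood apart for Gdf15 at 5.46, replicate 3 for Angptl4 at 4.55, and replicate 4 for Bex3 at 9.58, Irs2 at 7.48, Nqo1 at 6.44 and the glucocorticoid score at 0.

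Camera called a difference between the day 3 and day 1 effects for glucocorticoid genes (median 0.247), branched-chain genes (-0.231), skeletal muscle markers (0.4) and mast cell markers (0.554), and between the day 14 and day 1 effects for branched-chain genes (-0.172) and erythroid markers (1.016). None of these held with an estimated correlation, where the adjusted p values were 0.657, 0.154, 0.882 and 0.154 for day 3 and 0.904 for both of day 14. Among transcript clusters without a single gene symbol, of which 22759 were tested beside those of named genes, 1 was called on day 3, 4 on day 14 and 106 in the mean of days (45 higher and 61 lower).

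The lower branched-chain and ketone oxidation genes on day 3 were set against 3 explanations. Differences between arrays that follow intensity were argued against: after cyclic loess the score difference was -0.276 (95% interval -0.402 to -0.15), against -0.301 (-0.423 to -0.178) before. A lower share of cardiomyocytes cannot be told apart: the fatty acid oxidation score had a difference 0.412 above that of the branched-chain score (0.265 to 0.56), but that list was itself called higher on day 3 and is no neutral measure of cell share, and the cardiomyocyte marker score differed by -0.023. With the clock score as a covariate the difference was -0.244 (-0.385 to -0.104), which met the bound set against a different clock phase. That score is an imperfect measure of phase, with genes picked after clock genes had been seen to differ. A different clock phase therefore cannot be told apart either. Feeding, growth and cage, which may differ between the arms, were not tested and stay open.

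The excess of lower over higher genes in the mean of days, 85.3% of 708, could be partly an effect of intensity. After cyclic loess 67.6% of 537 genes were lower, a share between the bounds set for the test. Centring each array on its median, which shifts all genes of an array alike, gave 68.5% of 482. The part due to intensity thus cannot be told apart from an offset between arrays or from a treatment effect. The effects correlated with mean intensity across genes, which are not independent replicates, at a Spearman rho of -0.294 in the mean of days. By day the rho was -0.133 on day 1, -0.108 on day 3 and -0.377 on day 14. On day 14 the number of calls went from 45 to 16 after cyclic loess, with 15 of the 16 lower, and to 12 with centring, with 11 of the 12 lower. An effect of intensity on the day 14 calls was not tested further.

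The clock gene Bmal1 fell in the mean of days (-0.68, adjusted p = 0.00821 by limma). The clock score (Bmal1, Npas2, Clock, Cry1 and Nfil3 minus Nr1d1, Dbp, Tef, Per3 and Ciart, 10 genes) differed by 0.087 on day 1, -0.877 on day 3, -0.696 on day 14 and -0.495 in the mean of days, with exact permutation p values of 0.771, 0.0571, 0.0857 and 0.0192 (the fixed clock list, which joins genes of opposite phase, had 0.0571, 0.8, 0.4 and 0.25). The genes of the score were picked after single clock genes had been seen to differ, so it cannot test whether the clock shifted. A bound written after single clock genes had been seen but before these p values were, by which p values of 0.05 or more on both days would count against a different time of necropsy, was met and then set aside, because the score is no independent test and a missed threshold with 70 reassignments does not show that the arms were alike. The labels give no time of necropsy, so a different time may account for the Bmal1 difference and cannot be told apart from an effect of metformin.

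Other splits of the same arrays were counted. For day 3 genes 1 of 35 splits, the real one, gave as many as 76, and the highest other gave 1. For day 14 genes it was 1 of 35 (45, highest other 1), and for the mean of days 1 of 100 (708, highest other 1). These ranks argue against chance for the 3 counts but do not exclude it. A share of 1 of 35 or 1 of 100 is the lowest possible. The other splits also mix the arms, so a treatment difference would widen their spread and lower their counts. Without 1 array the count was as low as 27 on day 3 and 11 on day 14. With only the arrays of that day it was 3 and 0. For control days 1 of 100 splits, the real one, gave as many, but the highest other split gave 18 against 26. That count was as low as 3 without 1 array and 0 with only the control arrays or the erythroid covariate, so it stands less firmly. For day 1 and for treatment by day the real count was 0, so all 35 and all 100 splits reached it by construction, which says nothing about chance (highest others 1 and 38). None of the camera list counts argued against chance. At least 7 lists were called in 14 of 35 splits on day 1 (highest other 15) and in 29 of 35 on day 3 (16). At least 6 were called in 26 of 35 on day 14 (14), and at least 7 in 59 of 100 in the mean of days (19). The camera calls of single lists carry this limit. The exact permutation of scores, which uses the spread between arrays alone, gave 9 of 41 lists an adjusted p under 0.05 in the mean of days. This count is for the deposited scaling. Of the 9 lists, only FOXO and PPAR-alpha genes also passed after quantile normalization, centring and cyclic loess alike.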

How the results depend on the processing

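The tests with cyclic loess, the covariates and the removal of 2 arrays, and all repeats of the branched-chain list test between control days, were chosen after the results were seen. Under settings other than single arrays left out, 1624 of 1815 values of named genes and 189 of 249 of lists kept their direction and side of the threshold, 162 and 58 lost the call, 22 and 0 gained one, and 7 and 2 changed direction. Without single arrays 1678 of 1840 and 301 of 340 kept both, 135 and 38 lost the call, 9 and 0 gained one, and 18 and 1 changed direction. The gene totals include genes that were not called in the main fit and so had no call to lose. Under the other settings the named calls lost ran from 0 to 20 of 21 on day 3. They ran from 0 to 14 of 14 on day 14 and from 0 to 5 of 31 in the mean of days. Called without each array in turn were 9 of 21, 3 of 14 and 29 of 31. The cause was not tested for any of the changes below, which include fits with fewer arrays or other numbers of genes and thresholds. Dim genes and genes near the ceiling of the scale limit what can be resolved.

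With only the arrays of that day, 11 lists were called on day 1, and 3 genes on day 3 and 0 on day 14, and with only the control arrays 0 genes differed between days. With no filter on dim genes 48 genes were called on day 3 and 6 between control days, and 14 lists in the mean of days. A stricter filter gave 146 genes on day 3 and 124 on day 14. Testing every transcript cluster on its own gave 21, 15 and 411 on day 3, day 14 and the mean of days, and 5 between control days. Quantile normalization again gave 42, 8 and 384, and Nppa in the mean of days was 0.03. Centring each array on its median gave 37 on day 3, 12 on day 14 and 5 between control days, with Myh7 at 0.009. Array quality weights gave 3 on day 1, 83 on day 14 and 65 between control days. An added 1.5-fold threshold gave 28, 11 and 22 on day 3, day 14 and the mean of days, and 8 between control days. A looser adjusted p of 0.1 gave 207, 231 and 1182. Unadjusted p with 1.5-fold gave 71 on day 1, 107 on day 14, 42 in the mean of days, 172 for treatment by day and 113 between control days.

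Camera with an estimated correlation called 0 lists on day 1, 0 on day 3, 0 on day 14 and 0 in the mean of days, and fry called 0, 4 and 2 on days 1, 3 and 14 and 7 in the mean of days. Cyclic loess gave 16 genes on day 14 and 6 between control days, with Myh7 at 0.001. The erythroid level as a covariate gave 379 in the mean of days and 0 between control days, and an erythroid list p of 0.886 on day 1 with the opposite direction. That covariate is the mean of the same erythroid markers, so this list result was largely fixed in advance. It is among the list results counted above as changed in direction. The clock score as a covariate gave 26 genes on day 3, 27 on day 14, 437 in the mean of days and 16 between control days, 12 lists on day 1 and 4 on day 3, and Nppa at 0.129. Without both arrays with muscle or blood markers, 29 genes were called on day 3 and 9 between control days, 13 lists on day 1, Myh4 on day 1 was 0.048, Slc16a1 was -0.007, Nppa was 0 and the skeletal muscle list p was 0.337 on day 1 with the opposite direction.

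Replicate numbers showed no clear pairing of the animals. Over 12 pairs the correlations of deviations ran from -0.148 to 0.11, 2 were over 0.1, and 1 control array correlated best with its own number. With 4 arrays per group these values do not exclude a shared cage or batch, which the labels do not give. With the replicate block 67, 49 and 648 genes were called on day 3, day 14 and the mean of days, and 6 between control days. With the replicate block within day the counts were 29, 24 and 378, and no value for control days was possible.

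Leaving out each array in turn gave 27 to 144 genes on day 3, 11 to 142 on day 14, 528 to 827 in the mean of days, 0 on day 1, 0 for treatment by day and 3 to 28 between control days, and 4 to 14, 5 to 9, 3 to 8 and 5 to 12 lists on day 1, day 3, day 14 and in the mean of days. Differences that changed sign were those of Nppa (-0.371 to 0.262), Myh7 (-0.047 to 0.014), Slc16a1 (-0.015 to 0.062) and Txnip (-0.003 to 0.251) in the mean of days, Pdk4 on day 14 (-0.628 to 0.338) and Myh4 on day 1 (-1.413 to 0.048), and the skeletal muscle list p on day 1 ran from 0.000576 to 0.329.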

Other observations

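The exact permutation of list scores, its repeats under other scalings and the genes named here were chosen after the values were seen. Zbtb16, a transcription factor induced by glucocorticoids, rose in the mean of days by 1.52 (SE 0.27, adjusted p = 0.0029 by limma, n = 4 per arm and day), and the rise lay between 1.39 and 1.66 with any single array left out. The glucocorticoid list as a whole had a median of -0.19 over 22 members, with 1 rising and 3 falling. Acta1, skeletal alpha-actin, rose by 0.74 (SE 0.18, adjusted p = 0.0229), with the cardiac stress list at a median of -0.01. The Acta1 call was lost with the erythroid covariate (0.63, adjusted p = 0.092), the clock covariate (0.76, 0.0673), without both arrays with muscle or blood markers (0.65, 0.0626) and with the replicate block within day (adjusted p = 0.077). Bmal1 fell by 0.68 (SE 0.14, adjusted p = 0.00821), and Nr1d1 differed by 0.71 (SE 0.27, adjusted p = 0.151).

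In the mean of days the exact permutation also passed for 4 lists that camera did not call. These were AMPK subunits and biogenesis regulators (score difference -0.076), calcium handling and contractile genes (-0.05) and cardiomyocyte markers (-0.021), each with an adjusted permutation p of 0.0183, and NRF2 antioxidant genes (-0.093, 0.0378). None of the 4 passed after quantile normalization, centring or cyclic loess, and the score difference of cardiomyocyte markers was 0.006 after centring. Under the same 3 scalings FOXO and atrophy genes passed each time (0.00717, 0.0299 and 0.0172), as did PPAR-alpha genes (0.0325, 0.0402 and 0.0258). Branched-chain genes (0.0482 and 0.027) and sterol synthesis genes (0.0402 and 0.027) passed after centring and cyclic loess, and immediate-early genes passed after cyclic loess (0.0457). The list of the tricarboxylic acid cycle and pyruvate dehydrogenase passed after cyclic loess alone (score difference 0.055, adjusted permutation p = 0.0373). Its adjusted permutation p was 0.386 with the deposited scaling.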
